A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 12 samples.

How the data were processed

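The samples were 12 RNA-seq libraries of Synechococcus elongatus PCC 7942, 3 each of WT and of strains carrying PebA with PebB, PcyX or PebS, grouped by the strain that GEO's labels name and numbered as the labels number them. Per the labels' protocols the cells grew at 30 °C under 60 µmol photons per square metre and second of white light and 2% CO2. Total RNA was taken on day 4 and depleted of ribosomal RNA, and directional libraries with inserts of about 200 bp were made from it. The series' design text calls the samples biological replicates. Nothing further says how separately the cultures were kept, so the p-values measure the spread between these samples, which may be partly technical.

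The deposited table holds 1 TPM value per gene and sample, per the file headers, where TPM is the read count per unit of coding length scaled to the same sum in each sample. The aligner, the counting method, whether it used strand and the genome build are not given in the sources used here beyond the sequence names in the table. Without a statement on strand, reads of overlapping or antisense genes cannot be assigned with certainty. Gene names, products and coordinates are those of the table, counted from 1. Coding lengths were multiples of 3 for 100% of genes, so the models hold no untranslated parts. None of the table's locus tags (0 of 2673) matched the gene table given with the data, which is of another assembly, so no further names were added. Products were hypothetical, unknown or uncharacterized for 1046 genes.

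TPM keeps no depth by itself, but TPM times coding length fell on whole multiples of 1 step per sample for 100% of values, within 0.05 of a whole number, and these multiples were taken as recovered reads. They sum to 776728 to 852721 in sample 1 of the strains and to 2160514 to 4017081 in samples 2 and 3. The median gene held 57 to 69 reads in sample 1 and 181 to 367 in the others. For an introduced gene at 0 reads in a sample, a floor of 3 reads in that sample was used, which covers counting error only. Samples of 1 strain differed by far more than counting error (chi-square over degrees of freedom 6.28 to 42.3), so none was taken as a library deposited under 2 names. The table's columns for sample 1 lack the sequencing index that those of samples 2 and 3 carry, and counts were repeated within samples 2 and 3.

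Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2(TPM + 1), with a mean for each strain over all 12 samples, so that all groups share 1 estimate of the spread. Genes with a mean of at least 5 TPM were tested (2574 genes, with 99 below). P-values were two-sided and adjusted by Benjamini-Hochberg within each of 6 comparisons, and an adjusted p under 0.05 counted as a change. The 3 contrasts against WT also entered a moderated F-test. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

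Before the data were examined, 29 gene lists were fixed by patterns in gene symbols and product texts, covering the antenna, pigment synthesis, photosynthesis, carbon, nitrogen, stress, regulation and the plasmid. The list of ribosomal and transfer RNA was left out because the table lists no RNA genes. The introduced enzymes were read singly, as was phycobilisome degradation (NblA), which has fewer than 3 tested members, so that 26 lists were tested. Each was compared with the other genes by camera with a preset correlation of 0.01 and again with an estimated correlation, and by fry, which does not compare a list with other genes. Adjusted p-values of lists were taken over the 26 lists of a comparison. Values with samples left out or rescaled keep the preset correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

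The genes named in the text follow a rule fixed at the same time. It takes the introduced enzymes and, for each strain against WT, the 8 largest rises and 8 largest falls. These need an adjusted p under 0.05, all 3 samples on 1 side of the 3 WT samples, and a symbol or a named product. It adds, for each list, up to 4 passing members by size of change or, where none passes, the 2 members with the highest mean TPM as values, and 4 genes in each direction between strains. The introduced genes carry symbols and so fill places among the largest changes too.

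The labels give every strain samples 1, 2 and 3. Deviations from the strain means correlated across genes between samples of the same number for every pair of strains, at r = 0.693 to 0.734 for sample 1, 0.397 to 0.556 for sample 2 and 0.644 to 0.696 for sample 3, and 11 of 12 samples correlated best with their own number. The numbers were therefore taken to pair the samples, on the strength of the data and not of the labels, and a fit with the number as a block was set beside the fit without it where it changes a call.

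Other alternatives were pseudocounts of 0.1 and 5 TPM, no minimum and a minimum of 20 TPM, median-ratio scaling, quantile normalization, TPM without the introduced enzymes, eBayes without a trend and with a robust trend, sample weights, fits of only the strains compared, and leaving out each sample in turn. Added after the data were seen were samples 2 and 3 alone, voom on recovered reads with and without the block, the block with median-ratio scaling or an estimated correlation, lists completed with locus tags or without members of another function, groupings that keep the sample numbers, and sums over near-identical copies (phycocyanin, psbA and psbD). The closing section gives their effect. Overlap between strains was set beside 100 simulated sets of unchanged strains against the same WT samples.

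Run first on 2559 simulated genes, the test recovered 16.7% of genes changed 1.5-fold in PebAB against WT, 46.3% at 2-fold and 90.8% at 4-fold. False calls numbered 0, and 3 with the block, which recovered 50.0%, 79.1% and 96.9%. A shifted list of 20 genes had adjusted p = 9.04e-17 and 0 of 50 unchanged lists were called. No list of correlated genes was run.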

Results

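Transcript levels were measured by RNA-seq in Synechococcus elongatus PCC 7942, a unicellular freshwater cyanobacterium. Its light-harvesting phycobilisomes are built of phycocyanin and allophycocyanin and carry the blue bilin phycocyanobilin. The wild type (WT) was set beside 3 strains that overexpress phycoerythrobilin synthases, ferredoxin-dependent enzymes that reduce biliverdin to the red bilin phycoerythrobilin. The PebAB strain carries PebA and PebB, which act in sequence. The PebS strain carries PebS, a phage enzyme that catalyses both steps, and the PcyX strain carries PcyX, another enzyme found in phage sequences that makes the same pigment. The study's title sets out a comparison of these synthases for tuning phycobilisomes. Cells were grown in continuous white light with 2% CO2 and harvested on day 4, with 3 biological replicates per strain.

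The deposited table gave the transcript level of 2673 genes as TPM, a read share scaled by coding length and sample total, of which 2611 lie on the chromosome, 58 on the large plasmid and 4 on the introduced vectors. Whole reads recovered from the TPM values came to 776728, 3362385 and 2160514 in WT samples 1, 2 and 3. The PebAB samples held 819509, 3488194 and 2482639 reads in the same order, the PcyX samples 852721, 4017081 and 2283206 and the PebS samples 835471, 3177501 and 2409021. Sample 1 of each strain was thus the shallowest. TPM values are given as mean ± SD over the 3 samples of a strain, and changes as differences of mean log2(TPM + 1) ± standard error, a scale that understates the change of genes with few reads. Adjusted p-values are two-sided values from limma over the 2574 genes with a mean of at least 5 TPM.

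The introduced genes were read first, as a check of the labels. In the PebAB strain pebA stood at 2559.9 ± 255 TPM and pebB at 1406 ± 26.1 TPM (n = 3 each). PcyX transcripts (pcyX_cme in the table) stood at 2341 ± 1205 TPM in the PcyX strain, from 1308 to 3666 TPM, a range of 2.80 times between its samples. PebS transcripts (pebS_cme) stood at 2265 ± 792 TPM in the PebS strain, from 1416 to 2984 TPM. No WT sample held a read of any of the 4 genes. Against a floor of 3 reads in the shallowest WT sample, which bounds counting error only, the transcripts were at least 609-fold (pebA), 368-fold (pebB), 525-fold (pcyX_cme) and 524-fold (pebS_cme) higher than in WT. On the vectors pebA spans positions 7409 to 8140, pebB 8137 to 8940, pcyX_cme 7409 to 8098 and pebS_cme 7409 to 8119, all as coding sequence without untranslated parts. The reading frames of pebA and pebB overlap, so a read across the junction could have been given to either gene.

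**Figure D1:**
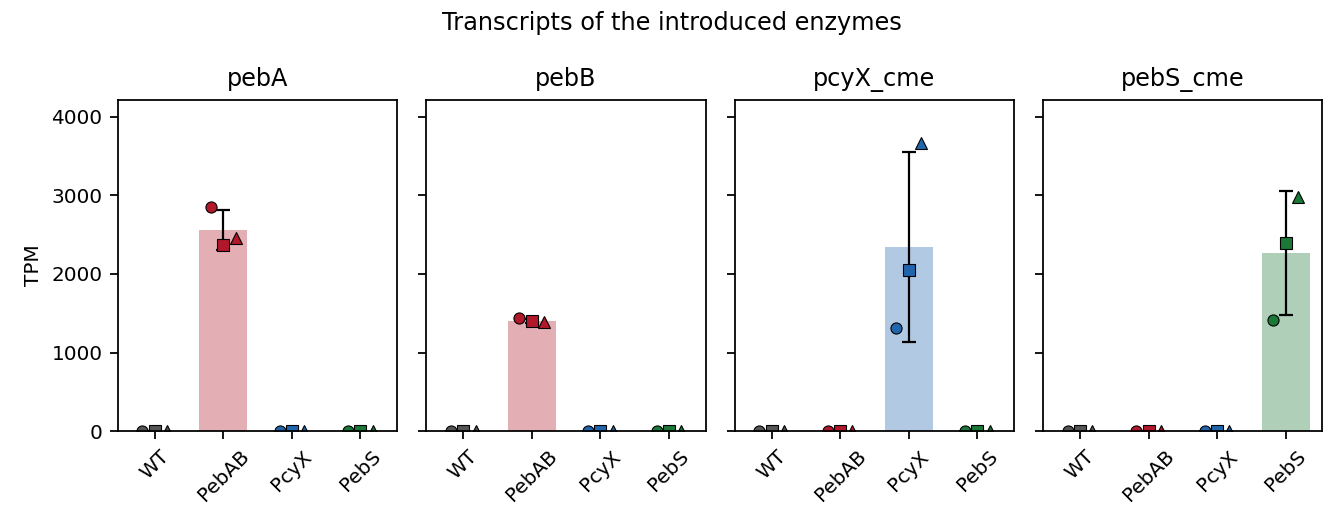
TPM (vertical axis) of the 4 introduced genes in WT and the 3 strains; bars are means, error bars are SD, and circles, squares and triangles are samples 1, 2 and 3. Each gene stood at 1308 TPM or higher in every sample of the strain that carries it and at 0 TPM in the 3 WT samples.

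Among the 12 samples, the first principal component of log2(TPM + 1) held 33.3% of the variance and parted sample 1 of every strain from samples 2 and 3. Sample 1 lay at -23.3 (WT), -14.9 (PebAB), -23.4 (PcyX) and -21.8 (PebS), the other 8 samples between 0.826 and 18.8. The second component, with 28.5%, parted PebAB (31.0, 19.4 and 20.5) from the 9 samples of the other strains (-14.0 to 1.02). Within strains the samples correlated at r = 0.928 to 0.989 across genes, which are not independent replicates. Over all 4 strains, 817 of the 2574 genes differed by limma's moderated F-test, and 1724 with the sample number as a block.

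**Figure D2:**
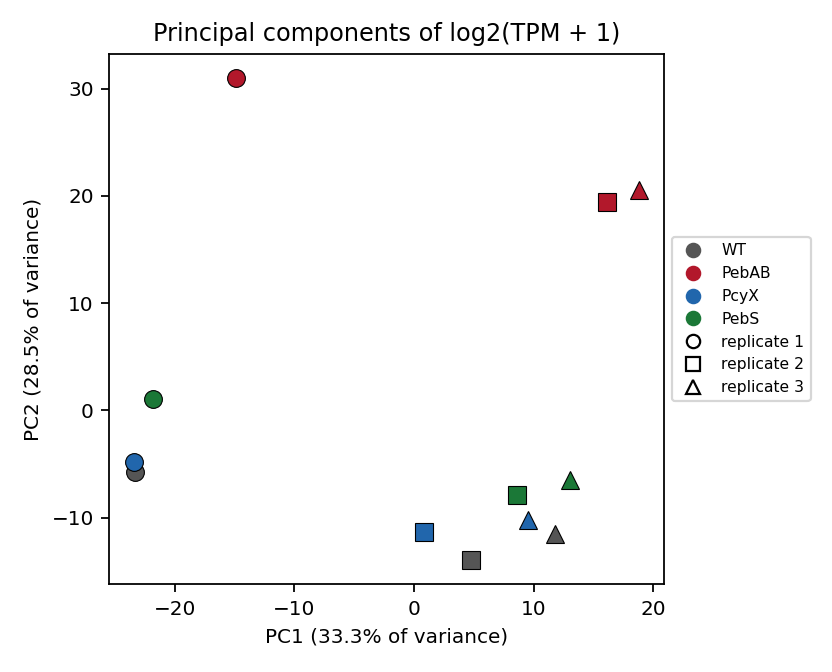
The 12 samples on the first principal component (horizontal axis, 33.3% of the variance) and the second (vertical axis, 28.5%) of log2(TPM + 1); colours are strains and marker shapes are sample numbers. Sample 1 of each strain lies at -14.9 or lower on the first component, and the 3 PebAB samples lie at 19.4 or higher on the second.

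PebAB was first set against WT. The group 2 sigma factor SigC (Synpcc7942_1849, chromosome 1916620 to 1917816), an alternative subunit that directs RNA polymerase to promoters, stood at 6185 ± 1815 against 136 ± 37.2 TPM, a rise of 5.48 ± 0.29 (adjusted p = 2.48e-07). Transcripts of a protein related to the ChlI subunit of magnesium chelatase (Synpcc7942_1391, chromosome 1436154 to 1437692) rose from 8.62 ± 0.813 to 133 ± 9.23 TPM (3.80 ± 0.16, adjusted p = 4.00e-08). The A subunit of the potassium-transporting ATPase (Synpcc7942_1668, chromosome 1737882 to 1739552), a high-affinity potassium pump, rose from 25.5 ± 3.92 to 317 ± 27.9 TPM (3.59 ± 0.13, adjusted p = 1.60e-08). A thiosulphate-binding protein (Synpcc7942_1681) rose by 3.58 ± 0.31, adjusted p = 1.19e-05, and the gamma subunit of the bidirectional hydrogenase (Synpcc7942_2557, chromosome 2635638 to 2636354) by 3.42 ± 0.30, adjusted p = 1.22e-05. A small gene listed as possible ribosomal protein L36 (Synpcc7942_1567) rose by 3.44 ± 0.27, adjusted p = 5.60e-06.

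The falls in PebAB were smaller. Rubrerythrin (Synpcc7942_1649, chromosome 1716788 to 1717504), a non-heme iron protein that reduces peroxides, stood at 18.4 ± 7.91 against 76.2 ± 17.7 TPM (-2.04 ± 0.30, adjusted p = 0.000660). A transcriptional regulator with a cupin domain (Synpcc7942_2038, chromosome 2107367 to 2108059) changed by -1.86 ± 0.21, adjusted p = 8.63e-05. A gene listed as chlorophyll synthase or NADPH-protochlorophyllide oxidoreductase (Synpcc7942_2503, chromosome 2584495 to 2585460) fell from 999 ± 109 to 398 ± 43.8 TPM (-1.32 ± 0.12, adjusted p = 1.84e-05). A fasciclin-domain protein (Synpcc7942_1606, -1.45, adjusted p = 2.51e-05), a phospholipid/glycerol acyltransferase (Synpcc7942_1193, -1.32, adjusted p = 8.63e-05), an acetylpolyamine aminohydrolase (Synpcc7942_2124, -1.48, adjusted p = 0.00191) and the plasmid gene anL21 (large plasmid 14905 to 15528; -1.77, adjusted p = 0.00593) also fell. Sulfiredoxin (Synpcc7942_0108) changed by -1.71 ± 0.46, adjusted p = 0.0208, a call lost without WT 1 (adjusted p = 0.0726) or PebAB 2 (0.0772), under median-ratio scaling (0.0620) and after quantile normalization (0.0575).

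In total 616 genes differed between PebAB and WT, 181 higher and 435 lower, and 159 of them changed at least 2-fold, 123 higher and 36 lower. The median change of all tested genes was -0.24, so that a gene at this median already had a negative change, though not by that alone a call. After median-ratio scaling, which removes that shift, 389 genes differed, 244 higher and 145 lower, and the share of higher calls moved from 29.4% to 62.7%. At 2-fold 149 were then higher and 18 lower. Quantile normalization gave 217 higher and 244 lower, and 132 and 22 at 2-fold. Relative to the median, SigC rose by 5.73 and Synpcc7942_2503 stood at -1.08. With the sample number as a block 1325 genes differed, within samples 2 and 3 of each strain 623, and without WT 2 385. Within samples 1 alone there is 1 sample per strain and no value could be had.

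Of 26 gene lists fixed beforehand, 3 rose in PebAB against the other genes. In the circadian clock list 3 of 4 members rose, and its median lay 1.82 above that of all tested genes (adjusted p = 0.00145 by camera, 0.0899 with an estimated correlation). These were KaiC (Synpcc7942_1216, 2.57, adjusted p = 4.40e-06), KaiB (Synpcc7942_1217, 2.36) and KaiA (Synpcc7942_1218, 0.80), the proteins of the circadian oscillator. In the list of glycogen and storage carbon 3 of 5 members rose and 1 fell (3 and 2 adjusted over the list alone, 3 and 0 under median-ratio scaling), with a median 2.19 above that of all genes (adjusted p = 0.00949 by camera, 0.134 with an estimated correlation). The risers were glucose-6-phosphate dehydrogenase (Synpcc7942_2334, chromosome 2401339 to 2402874), the first enzyme of the oxidative pentose phosphate pathway, at 557 ± 9.96 against 81.4 ± 11.7 TPM (2.77 ± 0.10, adjusted p = 1.60e-08), glycogen phosphorylase (Synpcc7942_0244, 2.20) and glycogen debranching enzyme (Synpcc7942_1575, 1.94). Glucose-1-phosphate adenylyltransferase (Synpcc7942_0603), which makes the precursor of glycogen, stood at -0.49 (adjusted p = 0.0142, 0.208 under median-ratio scaling). Among 7 sigma factors 3 rose, with a list median 0.46 above that of all genes (adjusted p = 0.0156 by camera, 0.437 with an estimated correlation), namely SigC, the principal factor SigA (Synpcc7942_1557, 1.02, adjusted p = 6.69e-06) and SigD (Synpcc7942_0672, 0.90, adjusted p = 0.0294). The SigD call was lost within samples 2 and 3 (adjusted p = 0.0647) and without WT 1 (0.0938), WT 2 (0.0868), PebAB 2 (0.0646) or PebAB 3 (0.0990).

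4 lists fell in PebAB. In ATP synthase 6 of 9 subunits fell (8 adjusted over the list alone, 2 under median-ratio scaling), among them the F0 c subunit (Synpcc7942_0332, -0.85) and the F1 alpha subunit (Synpcc7942_0336, -0.71). The list's median lay at -0.47 relative to all genes (adjusted p = 0.00685 by camera, 0.420 with an estimated correlation). Of 4 listed NDH-1 subunits, parts of the NADPH dehydrogenase of the thylakoid, 3 fell (4 adjusted over the list alone, 2 under median-ratio scaling), with a relative median of -0.53 (adjusted p = 0.0156 by camera, 0.277 with an estimated correlation). Subunit 1 (Synpcc7942_1343) stood at -0.91 and subunit 6 (Synpcc7942_1345) at -0.83. In heme and bilin synthesis 6 of 12 members fell (8 adjusted over the list alone, 1 under median-ratio scaling), with a relative median of -0.18 (adjusted p = 0.0493 by camera, 0.437 with an estimated correlation). PcyA (Synpcc7942_1225, chromosome 1246181 to 1246927), which makes phycocyanobilin from biliverdin, fell from 464 ± 29.4 to 271 ± 49.2 TPM (-0.78 ± 0.13, adjusted p = 0.00156), and uroporphyrinogen decarboxylase (Synpcc7942_1086) stood at -0.70 (adjusted p = 0.00547, 0.0600 under median-ratio scaling). This list's call was lost under median-ratio scaling (adjusted p = 0.0889) and without WT 1 (0.176), PebAB 2 (0.135), PebAB 3 (0.0969), PebS 3 (0.0571), PcyX 1 (0.0503) or PcyX 2 (0.0502). All 4 genes of inorganic carbon uptake fell (1 under median-ratio scaling; adjusted p = 0.0436 by camera, 0.268 with an estimated correlation), led by the sodium-dependent bicarbonate transporter (Synpcc7942_1475, -1.30). That call was lost with the sample number as a block (0.113), under median-ratio scaling (0.0889), within samples 2 and 3 (0.0960) and without WT 1 (0.0623), WT 3 (0.0553), PebAB 2 (0.0733) or PcyX 1 (0.0503).

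None of the antenna genes passed in PebAB without the block. Phycocyanin is encoded in near-identical copies whose reads the counting could not place with certainty, so the copies were summed. The alpha copies Synpcc7942_1048 and Synpcc7942_1053 stood at 56777 and 7848 TPM in WT 1 and at 30011 and 29758 TPM in WT 2, with like splits in the other strains. The summed alpha subunit stood at 72727 ± 7263 TPM in PebAB and 62282 ± 2432 TPM in WT (log2 change 0.22, adjusted p = 0.301, 0.00554 with the sample number as a block). The beta subunit stood at 53455 ± 10992 and 45615 ± 6845 TPM (adjusted p = 0.447, 0.0111 with the block). None of the 9 phycocyanin rod genes (list adjusted p = 0.453) and none of the 5 allophycocyanin core genes (0.868) passed. With the block 3 rod genes were higher and 3 allophycocyanin genes lower (1 lower within samples 2 and 3). The allophycocyanin alpha chain (Synpcc7942_0327) stood at 10302 ± 1641 against 10937 ± 1710.3 TPM. NblA (Synpcc7942_2127), a small protein that triggers phycobilisome breakdown, stood at 138 ± 56.7 against 46.1 ± 10.5 TPM (adjusted p = 0.0516, 0.00620 with the block, 0.0472 under median-ratio scaling and 0.0245 within samples 2 and 3). It passed as well with only the PebAB and WT samples in the fit (0.0254) and without PcyX 1 (0.0322), PebS 1 (0.0288) or PebS 3 (0.0363). In PebS NblA stood as high, at 136 ± 87.7 TPM (adjusted p = 0.110, 0.0145 with the block, 0.0471 without PebS 3), and in PcyX at 96.1 ± 60.2 TPM (adjusted p = 0.462). Neither difference of Synpcc7942_2127 from PebAB passed (adjusted p = 0.874 and 0.399). In photosystem II, whose 24 genes did not move as a list (0.170), the summed psbA copies for the D1 protein rose from 18874 ± 554 to 43373 ± 835 TPM (1.20 ± 0.10, adjusted p = 1.23e-05), and the 12 kD extrinsic protein (Synpcc7942_1882) fell (-0.69, adjusted p = 9.59e-05).

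Further lists held changed members without moving as a whole in PebAB. Among 29 chaperones and proteases 3 rose and 5 fell (4 and 0 under median-ratio scaling; list adjusted p = 0.780), with the chaperonin GroEL (Synpcc7942_2313, 1.23) and GroES (Synpcc7942_2314, 1.18) among the risers. In oxidative and high-light stress 5 of 17 rose and 3 fell (5 and 1 under median-ratio scaling; 0.131), including catalase/peroxidase (Synpcc7942_1656, 1.67, adjusted p = 1.84e-05), 1-Cys peroxiredoxin (Synpcc7942_2449, 1.52, adjusted p = 0.000677) and glutathione peroxidase (Synpcc7942_1214, 0.87, adjusted p = 0.00400). In chlorophyll synthesis 3 of 7 rose and 2 fell (0.780), where geranylgeranyl reductase (Synpcc7942_0385) stood at -0.76 and the N subunit of the light-independent protochlorophyllide reductase (Synpcc7942_1420) at 0.67. In nitrogen assimilation 1 of 21 rose, an ammonium transporter (Synpcc7942_2279, 1.11), and 6 fell (2 and 3 under median-ratio scaling; 0.453), including nitrate transport subunits (Synpcc7942_1237, -0.79, and Synpcc7942_1236, -0.66) and a glutamine synthetase (Synpcc7942_0169, -0.65). Of 55 genes in the ribosomal list, which holds 54 ribosomal protein genes and a ribosomal protein methyltransferase (Synpcc7942_1500), 1 rose and 15 fell (2 and 0 under median-ratio scaling; 1 and 14 without the methyltransferase), and the list's adjusted p of 0.138 became 0.0130 with the block (0.185 with an estimated correlation added), 0.0215 within samples 2 and 3, 0.0451 without PebAB 1 and 0.0363 without WT 2. Cytochrome b6f and electron carriers (2 of 11 rose, 1 fell; 0.352) held apocytochrome f (Synpcc7942_1231, 0.50) and a cytochrome c6-like protein (Synpcc7942_2542, -1.06). Fatty acid synthesis (3 of 15 rose, 1 of them a carotene desaturase, Synpcc7942_1983, 2 fell, 3 and 0 under median-ratio scaling; 0.805) held a reductase (Synpcc7942_1573, 2.69), and iron homeostasis (1 of 14 rose, 2 fell, 2 and 1 under median-ratio scaling; 0.988) held pyruvate:ferredoxin oxidoreductase (Synpcc7942_2384, 2.19).

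The remaining lists gave adjusted p-values of 0.805 for carbon fixation (0 of 7 passing) and 0.988 for carotenoid synthesis (1 of 11 rose, 3 fell, 1 and 0 under median-ratio scaling). The pattern for carbon fixation missed both Rubisco subunits and carbonate dehydratase, and with them 3 of 10 were lower (0 under median-ratio scaling, 8 with the block; adjusted p = 0.276). Phosphate acquisition had 0.126 (1 of 7 rose, a phosphate-binding protein, Synpcc7942_2445, 1.10) and photosystem I 0.805 (2 of 12 fell, 0 under median-ratio scaling). The values were 0.406 for pili (0 of 12), 0.805 for plasmid-borne genes (1 of 40 rose, 4 fell, 2 and 2 under median-ratio scaling), 0.424 for sulfate assimilation (1 of 6 rose, sulfite reductase, Synpcc7942_0019, 1.27) and 0.886 for transposases (0 of 4). With the block, members higher and lower in PebAB numbered 0 and 5 in carbon fixation, 5 and 10 in chaperones, 3 and 2 in cytochrome b6f, 3 and 9 in fatty acids, 3 and 2 in glycogen and 2 and 6 in iron. They numbered 2 and 11 in nitrogen, 5 and 6 in oxidative stress, 1 and 1 in phosphate, 2 and 6 in photosystem I, 7 and 6 in photosystem II and 2 and 10 in plasmid-borne genes. The others numbered 2 and 35 in ribosomal proteins, 4 and 2 in sigma factors, 1 and 1 in sulfate and 0 and 2 in transposases. In 9 of the 26 lists, none of them called, the median, the mean and the direction of the test differed in sign: carotenoid, chaperones, chlorophyll, cytochrome b6f, fatty acid, iron, photosystem II, pili and sulfate.

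**Figure D3:**
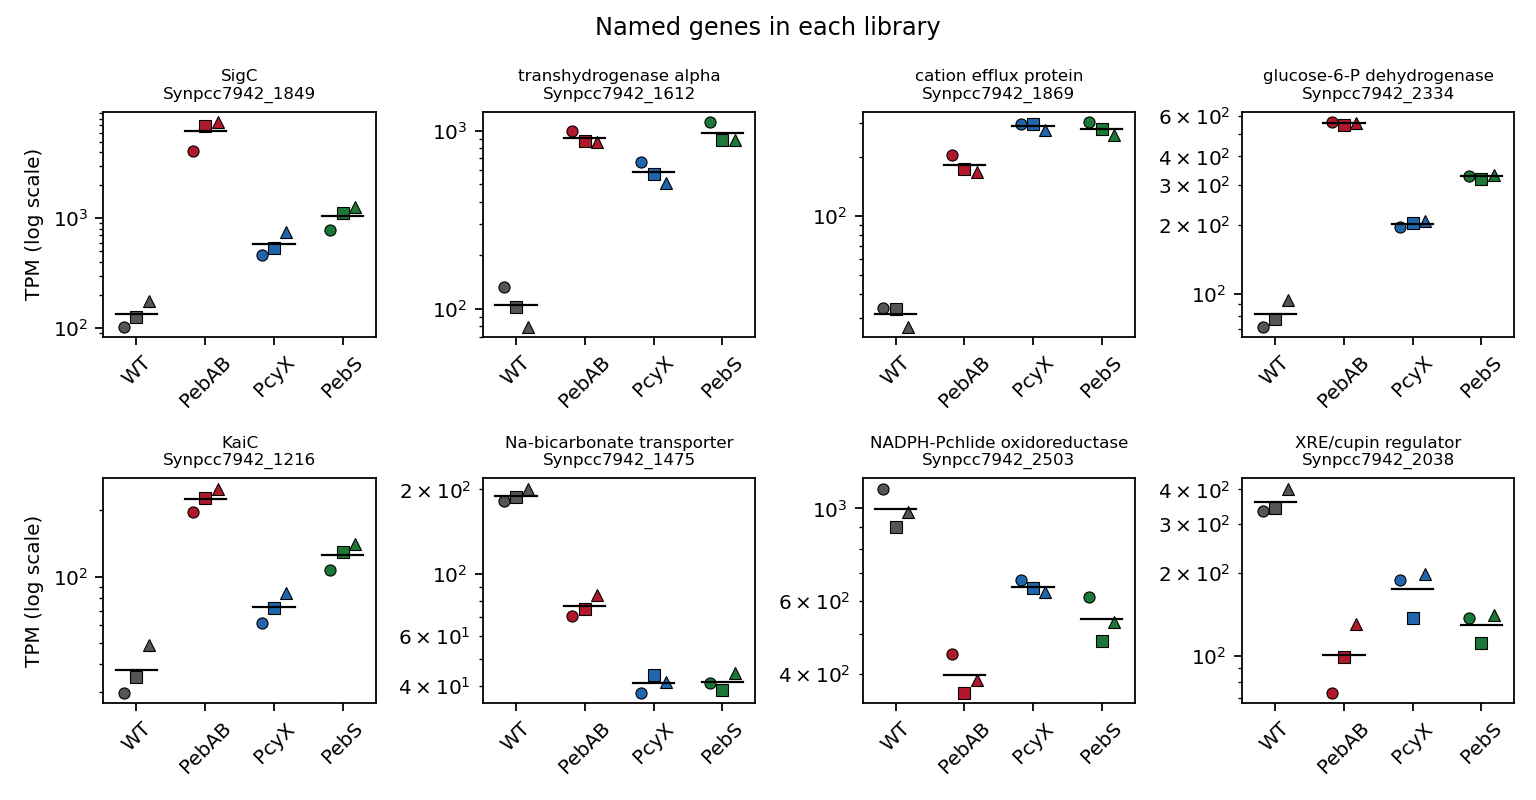
TPM (vertical log axis) per sample of SigC (Synpcc7942_1849), Synpcc7942_1612, Synpcc7942_1869, Synpcc7942_2334, KaiC (Synpcc7942_1216), Synpcc7942_1475, Synpcc7942_2503 and Synpcc7942_2038 in the 4 strains; short bars are means and markers are samples 1, 2 and 3. SigC stands at 6185 TPM in PebAB against 136 TPM in WT, and the bicarbonate transporter Synpcc7942_1475 at 40.9 TPM in PcyX against 190.2 TPM in WT.

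In PcyX against WT, the largest rise besides the introduced gene was in a probable cation efflux protein (Synpcc7942_1869, chromosome 1938280 to 1941534). It stood at 288 ± 12.4 against 31.5 ± 3.75 TPM (3.16 ± 0.12, adjusted p = 7.82e-08). The adjoining genes for the pyridine nucleotide transhydrogenase, which exchanges hydride between NAD and NADP, rose together. Synpcc7942_1610 stood at 551 ± 57.2 against 105 ± 3.28 TPM (2.38 ± 0.11, adjusted p = 3.22e-07). Synpcc7942_1611 rose by 2.55 ± 0.19, adjusted p = 1.43e-05 and Synpcc7942_1612 by 2.48 ± 0.18, adjusted p = 1.13e-05. SigC stood at 587 ± 150.0 against 136 ± 37.2 TPM (2.11 ± 0.29, adjusted p = 0.00133). A dehydrogenase subunit-like gene (Synpcc7942_1572, 1.97, adjusted p = 0.000188) and a pilin-like gene (Synpcc7942_2590, 1.85, adjusted p = 0.000550) also rose. The bicarbonate transporter Synpcc7942_1475 (chromosome 1525833 to 1526954), which imports bicarbonate with sodium, fell from 190.2 ± 10.2 to 40.9 ± 3.06 TPM (-2.19 ± 0.12, adjusted p = 1.00e-06). The small heat shock protein Hsp20 (Synpcc7942_2401) fell from 197 ± 34.8 to 71.1 ± 5.74 TPM (-1.45 ± 0.15, adjusted p = 0.000249). A cyclophilin-type peptidyl-prolyl isomerase (Synpcc7942_0653) changed by -1.30 ± 0.16, adjusted p = 0.000566 and anL21 by -2.31 ± 0.37, adjusted p = 0.00348. The regulator Synpcc7942_2038 changed by -1.05 ± 0.21, adjusted p = 0.0120, with adjusted p = 0.0561 without WT 3 and 0.0532 without PcyX 2.

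In total 151 genes differed between PcyX and WT, 126 higher and 25 lower, and 58 of them changed at least 2-fold, 46 higher and 12 lower. The median change of all genes was 0.07, and median-ratio scaling gave 114 genes, 83 higher and 31 lower (72.8% higher against 83.4%). The count was 501 with the sample number as a block, 57 with only the PcyX and WT samples in the fit, 125 within samples 2 and 3, and 99 without WT 3.

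8 lists moved in PcyX, and none of these calls was kept with an estimated correlation alone. With the block and an estimated correlation the plasmid-borne genes passed (adjusted p = 0.0120). Nitrogen assimilation rose, with 6 of 21 members higher (10 adjusted over the list alone, 3 under median-ratio scaling) and a median 0.30 above that of all genes (adjusted p = 0.000192 by camera, 0.158 with an estimated correlation). Nitrite reductase (Synpcc7942_1240) rose by 0.56 (adjusted p = 0.00345) and a nitrate transport subunit (Synpcc7942_1236) by 0.51 (adjusted p = 0.0111, 0.105 with only these strains, 0.0506 without WT 3 and 0.0528 without PcyX 2). Glycogen and storage carbon rose, with 3 of 5 members higher (adjusted p = 0.000365 by camera, 0.0797 with an estimated correlation): glycogen debranching enzyme (Synpcc7942_1575, 1.48, adjusted p = 0.00212), glucose-6-phosphate dehydrogenase (Synpcc7942_2334, 1.32, adjusted p = 1.92e-05) and glycogen phosphorylase (Synpcc7942_0244, 0.87, adjusted p = 0.00301). In fatty acid synthesis 2 of 15 rose (3 adjusted over the list alone; adjusted p = 0.0275 by camera, 0.325 with an estimated correlation), the reductase Synpcc7942_1573 (1.61) and enoyl-ACP reductase (Synpcc7942_0126, 0.74). The list holds 2 carotene desaturases by its product pattern, and its call was lost without them (adjusted p = 0.0597). It was also lost within samples 2 and 3 (0.0648), without WT 1 (0.160) and without PcyX 3 (0.125).

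Of the lists that fell in PcyX, the plasmid-borne genes had a median -0.58 relative to all genes, with 3 of 40 lower and none higher (adjusted p = 2.27e-08 by camera, 0.185 with an estimated correlation). Inorganic carbon uptake had 3 of 4 lower and 1 higher (adjusted p = 0.00316 by camera, 0.108 with an estimated correlation). The riser was Synpcc7942_2107 (0.56), which is also a member of the nitrogen assimilation list. The NDH-1 list had 1 of 4 lower (2 adjusted over the list alone), subunit 6 (Synpcc7942_1345, -0.45), with a relative median of -0.42 (adjusted p = 0.000822 by camera, 0.127 with an estimated correlation). Ribosomal proteins fell as a list by a relative median of -0.10 with 2 members higher, 1 of them the methyltransferase Synpcc7942_1500, and none lower (adjusted p = 0.0320 by camera, 0.185 with an estimated correlation; 0.0202 by camera without Synpcc7942_1500). The call was lost within samples 2 and 3 (adjusted p = 0.0724) and without WT 1 (0.348), WT 3 (0.0781), PcyX 2 (0.249) or PcyX 3 (0.0512). Chaperones and proteases had 2 of 29 lower (3 adjusted over the list alone), Hsp20 and Hsp70 (Synpcc7942_2468, -0.67), with a median of 0.02 and a mean of -0.14 that differ in sign (adjusted p = 0.0290 by camera, 0.185 with an estimated correlation). This call was lost with the block (0.0845), within samples 2 and 3 (0.0918) and without PcyX 1 (0.0769). With only the PcyX and WT samples in the fit, adjusted p was 0.0689 for Synpcc7942_2107, 0.0995 for Synpcc7942_1345 and 0.0537 for Synpcc7942_2468.

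The antenna lists were not called in PcyX: phycocyanin rods had adjusted p = 0.236 (0.0408 with the block, 0.167 with an estimated correlation added) and allophycocyanin 0.236, with no member passing (1 allophycocyanin gene lower with the block). Summed phycocyanin alpha stood at 57107 ± 4451 TPM against 62282 ± 2432 TPM (adjusted p = 0.816), and heme oxygenase (Synpcc7942_1858), which makes biliverdin, at a log2 change of -0.26 (adjusted p = 0.200, 0.0228 with the block). The other lists had adjusted p = 0.789 for heme and bilin synthesis, 0.0955 for photosystem I (0.0312 without PcyX 1), 0.422 for photosystem II. They were 0.330 for chlorophyll synthesis (2 of 7 rose, 1 fell, 1 and 1 under median-ratio scaling), 0.236 for the clock (2 of 4 rose, 1 under median-ratio scaling), 0.697 for cytochrome b6f (2 of 11 rose, Synpcc7942_1231, 0.66, and Synpcc7942_1232, 0.64). Sigma factors had 0.977 (2 of 7 rose, SigC and SigF, Synpcc7942_1784, 0.66). The values were 0.422 for pili (1 of 12 rose, 1 rose and 1 fell under median-ratio scaling), 0.906 for iron (1 of 14 rose, the pyruvate enzyme Synpcc7942_2384) and 0.904 for oxidative stress (1 of 17 rose, 0 under median-ratio scaling). ATP synthase (0.904), carbon fixation (0.977), carotenoid synthesis (0.789), phosphate acquisition (0.994), sulfate assimilation (0.989) and transposases (0.904) had no member passing. With Rubisco and carbonate dehydratase the carbon fixation list had 1 of 10 higher (0 under median-ratio scaling, 3 with the block). Members higher and lower in PcyX with the block numbered 1 and 0 in ATP synthase, 1 and 0 in carbon fixation, 2 and 0 in carotenoids, 1 and 4 in chaperones, 5 and 1 in chlorophyll and 5 and 2 in cytochrome b6f. They numbered 6 and 0 in fatty acids, 3 and 1 in heme and bilins, 3 and 0 in iron, 0 and 4 in NDH-1 complex, 11 and 1 in nitrogen and 2 and 0 in oxidative stress. The others numbered 1 and 2 in photosystem I, 5 and 6 in photosystem II, 3 and 1 in pili, 0 and 12 in plasmid-borne genes, 3 and 9 in ribosomal proteins and 2 and 3 in sigma factors. With only the PcyX and WT samples in the fit, Synpcc7942_1232 had adjusted p = 0.0533 and Synpcc7942_1784 0.0712.

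In PebS against WT transhydrogenase genes were among the largest rises. Synpcc7942_1612 (chromosome 1680679 to 1681905) stood at 967 ± 130.4 against 105 ± 27.0 TPM (3.21 ± 0.18, adjusted p = 7.40e-07). Synpcc7942_1611 rose by 3.20 ± 0.19, adjusted p = 1.09e-06 and Synpcc7942_1610 by 3.11 ± 0.11, adjusted p = 2.90e-08. The cation efflux protein Synpcc7942_1869 stood at 279.7 ± 21.2 against 31.5 ± 3.75 TPM (3.11 ± 0.12, adjusted p = 4.53e-08) and SigC at 1056 ± 254 against 136 ± 37.2 TPM (2.95 ± 0.29, adjusted p = 5.92e-05). The dehydrogenase subunit-like gene Synpcc7942_1572 (2.80, adjusted p = 5.61e-06) and the hydrogenase gamma subunit Synpcc7942_2557 (2.51, adjusted p = 0.000208) also rose. IsiA (Synpcc7942_1542, chromosome 1599353 to 1600381), the chlorophyll-binding protein made under iron shortage, rose from 7901 ± 1023 to 24109.6 ± 3233 TPM (1.61 ± 0.16, adjusted p = 7.59e-05). The bicarbonate transporter Synpcc7942_1475 fell to 41.3 ± 2.92 TPM (-2.18 ± 0.12, adjusted p = 4.79e-07) and the regulator Synpcc7942_2038 to 129 ± 15.8 TPM (-1.47 ± 0.21, adjusted p = 0.000740). Superoxide dismutase (Synpcc7942_0801, chromosome 795123 to 795812), which removes superoxide, fell from 656 ± 20.4 to 349 ± 38.9 TPM (-0.91 ± 0.14, adjusted p = 0.00147). The peptidyl-prolyl isomerase Synpcc7942_0653 (-1.39, adjusted p = 0.000150) and anL21 (-1.86, adjusted p = 0.00685) fell as well. The plasmid gene sepA2 (-0.99, adjusted p = 0.0168) lost its call with only these strains in the fit (0.0843), without WT 3 (0.0517) or without PebS 2 (0.0764).

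In total 354 genes differed between PebS and WT, 281 higher and 73 lower, and 121 of them changed at least 2-fold, 109 higher and 12 lower. Median-ratio scaling gave 324 genes, 219 higher and 105 lower, or 67.6% higher against 79.4%, and at 2-fold quantile normalization gave 85 higher and 19 lower. The count was 892 with the sample number as a block, 221 with only the PebS and WT samples in the fit, 351 within samples 2 and 3, and 221 without PebS 2.

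10 lists moved in PebS. The ribosomal list fell, with 12 of 55 members lower and 2 higher, 1 of these the methyltransferase Synpcc7942_1500 (16 and 2 adjusted over the list alone, 13 and 2 under median-ratio scaling) and a median -0.40 relative to all genes (adjusted p = 3.15e-11 by camera and 0.00648 with an estimated correlation). S2 (Synpcc7942_2530) fell from 911 ± 74.3 to 581 ± 45.2 TPM (-0.65 ± 0.10, adjusted p = 0.00126), L1 (Synpcc7942_0633) by -0.62, adjusted p = 0.00157, and the possible L36 gene Synpcc7942_1567 rose by 2.26. Glycogen and storage carbon rose, with 3 of 5 higher and a relative median of 1.26 (adjusted p = 0.000550 by camera and 0.0456 with an estimated correlation). Glycogen debranching enzyme (Synpcc7942_1575) rose by 2.13, glucose-6-phosphate dehydrogenase (Synpcc7942_2334) by 2.00 and glycogen phosphorylase (Synpcc7942_0244) by 1.33. These were the only calls of the 10 kept with an estimated correlation. With the block added to it, the ribosomal list kept its call and the glycogen list lost it (adjusted p = 0.0701). The clock genes rose, 3 of 4 (4 adjusted over the list alone; adjusted p = 0.00193 by camera, 0.0563 with an estimated correlation), with KaiC (Synpcc7942_1216) at 1.73, adjusted p = 0.000150 and KaiB (Synpcc7942_1217) at 1.52, adjusted p = 9.53e-05. Among genes of pili and DNA uptake 6 of 12 rose (7 higher and 1 lower adjusted over the list alone, 6 and 1 under median-ratio scaling; adjusted p = 0.00521 by camera, 0.0730 with an estimated correlation). They included the pilin-like gene Synpcc7942_2590 (2.28, adjusted p = 5.65e-05), PilM (Synpcc7942_2453, 0.72, adjusted p = 0.000377) and PilN (Synpcc7942_2452, 0.74, adjusted p = 0.00211). In nitrogen assimilation 8 of 21 rose (9 higher and 1 lower adjusted over the list alone, 3 and 0 under median-ratio scaling; adjusted p = 0.00242 by camera, 0.217 with an estimated correlation). The ammonium transporter Synpcc7942_2279 rose by 1.10, adjusted p = 0.00195 and nitrite reductase Synpcc7942_1240 by 0.64, adjusted p = 0.000648.

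Besides the ribosomal list, the plasmid-borne genes fell in PebS, with 3 of 40 lower and 1 higher (6 and 1 under median-ratio scaling; adjusted p = 0.000272 by camera, 0.321 with an estimated correlation). In NDH-1 2 of 4 fell (3 adjusted over the list alone; adjusted p = 0.00193 by camera, 0.0889 with an estimated correlation), subunit 4L (Synpcc7942_1346, -0.54) and subunit 6 (Synpcc7942_1345, -0.48). In inorganic carbon uptake 3 of 4 fell and 1 rose (3 and 0 under median-ratio scaling; adjusted p = 0.00673 by camera, 0.0730 with an estimated correlation). ATP synthase fell as a list with none of 9 genes passing (1 lower under median-ratio scaling), at a relative median of -0.30 (adjusted p = 0.00826 by camera, 0.321 with an estimated correlation). Its c subunit (Synpcc7942_0332) stood at 4234 ± 145 against 5222 ± 315 TPM (adjusted p = 0.0627, 0.000902 with the block, 0.0323 under median-ratio scaling and 0.00915 with voom weights on recovered reads). The list's call was lost without WT 1 (adjusted p = 0.0849). Heme and bilin synthesis fell as a list with none of 12 genes passing (3 lower adjusted over the list alone, 1 lower under median-ratio scaling; adjusted p = 0.0195 by camera, 0.321 with an estimated correlation). It lost its call without WT 1 (0.120) or PebS 2 (0.0644). Heme oxygenase (Synpcc7942_1858) stood at 1712 ± 70.9 against 2119.9 ± 172 TPM (adjusted p = 0.0704, 0.00632 with the block and 0.0235 with voom weights on recovered reads).

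Of the antenna genes none passed in PebS without the block, where 4 of 5 allophycocyanin genes and 1 of 9 rod genes were lower with it (1 allophycocyanin gene within samples 2 and 3). The allophycocyanin list had adjusted p = 0.0509, which became 0.00399 with the block (0.296 with an estimated correlation added) and 0.0184 within samples 2 and 3. It was 0.00553 without PebS 1, 0.0342 without WT 2, 0.0162 without WT 3, 0.0396 without PebAB 1, 0.0486 without PebAB 3 and 0.0475 without PcyX 3. The alpha chain (Synpcc7942_0327) stood at 8463 ± 1335 against 10937 ± 1710.3 TPM (adjusted p = 0.270, 0.000371 with the block). The phycocyanin rods had adjusted p = 0.260, and summed phycocyanin alpha stood at 57868 ± 4137 TPM (adjusted p = 0.731). The block also moved the adjusted p of carbon fixation from 0.114 to 0.00484 and of photosystem I from 0.114 to 0.0200, calls lost with an estimated correlation added (0.0701 and 0.0873). Samples 2 and 3 alone gave 0.0110 and 0.0310. With Rubisco and carbonate dehydratase 3 of 10 carbon fixation genes were lower (7 with the block) and the list passed (adjusted p = 0.00268, and 0.04997 with an estimated correlation), as did allophycocyanin with a core component its pattern missed (0.0266, but 0.524 with an estimated correlation). The other lists had adjusted p = 0.376 for photosystem II (1 of 24 fell), 0.429 for iron (4 of 14 rose, with IsiA and pyruvate:ferredoxin oxidoreductase, Synpcc7942_2384, 1.56). Sigma factors had 0.448 (3 of 7 rose, 2 rose and 1 fell under median-ratio scaling) and chlorophyll synthesis 0.608 (2 of 7 rose, 1 fell). The values were 0.114 for chaperones (3 of 29 fell), 0.965 for oxidative stress (2 of 17 rose, 2 fell, 0 and 2 under median-ratio scaling), 0.591 for fatty acids (2 of 15 rose, 2 rose and 1 fell under median-ratio scaling) and 0.815 for carotenoids (1 of 11 fell, 0 under median-ratio scaling). No member passed in cytochrome b6f (0.548), phosphate acquisition (0.815), sulfate assimilation (0.965) or transposases (0.806). In PebS, members higher and lower with the block numbered 0 and 7 in ATP synthase, 0 and 4 in carbon fixation, 1 and 1 in carotenoids, 3 and 6 in chaperones, 3 and 2 in chlorophyll, 2 and 2 in cytochrome b6f and 2 and 1 in fatty acids. They numbered 0 and 4 in heme and bilins, 5 and 2 in iron, 0 and 4 in NDH-1 complex, 11 and 1 in nitrogen, 6 and 2 in oxidative stress, 1 and 0 in phosphate and 0 and 4 in photosystem I. The others numbered 6 and 6 in photosystem II, 8 and 1 in pili, 2 and 8 in plasmid-borne genes, 2 and 43 in ribosomal proteins, 3 and 3 in sigma factors, 2 and 0 in sulfate and 1 and 0 in transposases.

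**Figure D4:**
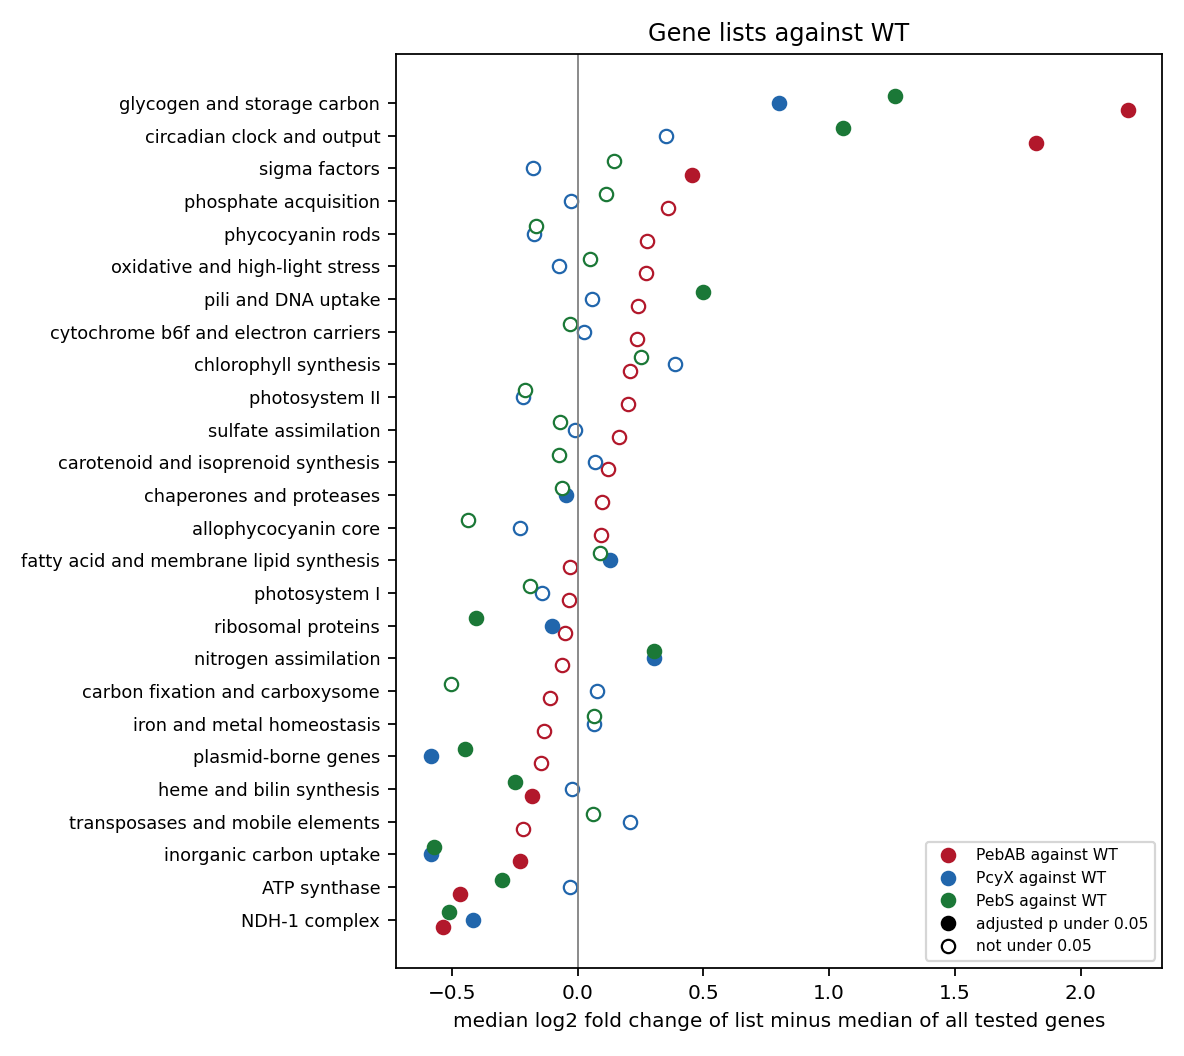
Median log2 change of each gene list minus that of all tested genes (horizontal axis) in the 3 strains against WT; filled markers have a camera adjusted p under 0.05. Glycogen and storage carbon lies at 2.19, 0.80 and 1.26 in PebAB, PcyX and PebS and ATP synthase at -0.47, -0.03 and -0.30.

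The changes of the 3 strains against the same WT samples overlapped. 64 genes were higher in all 3 strains and 14 lower, where independent lists would share 0.949 and 0.120 genes and 100 simulated sets of unchanged strains against these WT samples gave at most 0. The 64 had median changes of 2.35 in PebAB, 1.17 in PcyX and 1.76 in PebS. Among them, glyceraldehyde-3-phosphate dehydrogenase (Synpcc7942_0245) stood at 1080.3 ± 18.4, 364 ± 16.1 and 592 ± 29.6 TPM in PebAB, PcyX and PebS against 119.9 ± 14.2 TPM in WT. Also among the 64 were 6-phosphogluconate dehydrogenase (Synpcc7942_0039; 1.67, 1.01 and 1.85), the type 2 NADH dehydrogenase (Synpcc7942_0198; 2.21, 0.82 and 1.59) and the hydrogenase subunits Synpcc7942_2556 and Synpcc7942_2557. Potassium ATPase subunits Synpcc7942_1668, Synpcc7942_1669 and Synpcc7942_1671, the transhydrogenase genes Synpcc7942_1610 to Synpcc7942_1612, KaiB, KaiC and SigC were also among them. The 14 lower genes had medians of -0.86, -0.79 and -0.85 and included the bicarbonate transporter Synpcc7942_1475, the CO2 hydration proteins Synpcc7942_0308 and Synpcc7942_2093, NDH-1 subunits Synpcc7942_1344 and Synpcc7942_1345, Hsp20, Hsp70, Synpcc7942_2038 and Synpcc7942_2503. With the block 136 and 73 genes were shared, with only the samples of the strains compared 34 and 5, within samples 2 and 3 58 and 14, and without WT 2 53 and 9. The lower count was 8 without PebAB 2 or PebAB 3 and 9 without PcyX 1, PcyX 2 or PcyX 3. These genes were named from the shared set after its values were seen.

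Across 2570 genes, PcyX and PebS changes correlated at r = 0.783 (highest simulated 0.606). PebAB had 0.650 with PebS and 0.514 with PcyX, below the highest simulated (0.662 and 0.629). Covariances were 0.175, 0.233 and 0.144 against mean simulated 0.0554, 0.0564 and 0.0573. The differences of 0.119, 0.176 and 0.0867 estimate, without the block, the part not from common WT samples. With the block no simulated values were at hand. PcyX and PebS shared 113 higher and 20 lower genes with 1 in opposite directions, PebAB and PebS 117, 50 and 40, and PebAB and PcyX 67, 16 and 17. Independent lists would share 13.6 and 0.710, 19.5 and 12.4, and 8.71 and 4.23 higher and lower genes. With the block these counts were 279, 100 and 7, 221, 232 and 134, and 142, 90 and 106, where independent lists would share 81.3 and 16.9, 71.6 and 122, and 44.7 and 54.4. WT had too few samples to be split into sets of 2, so part of the excess may come from the shared controls.

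PebS and then PcyX were set against PebAB. The number and level of introduced transcripts differ too, so differences cannot be credited to the enzymes alone. Besides the introduced genes, a probable glycosyltransferase (Synpcc7942_2026, chromosome 2094451 to 2095854) stood at 370.5 ± 63.2 against 46.4 ± 3.66 TPM in PebS against PebAB (2.96 ± 0.15, adjusted p = 4.77e-07). The fasciclin-domain protein Synpcc7942_1606 (chromosome 1671451 to 1672011) stood at 418 ± 47.7 against 69.7 ± 5.02 TPM (2.57 ± 0.14, adjusted p = 7.28e-07). The pilin-like gene Synpcc7942_2590 stood at 129.5 ± 21.3 against 21.2 ± 0.790 TPM (2.55 ± 0.22, adjusted p = 2.66e-05). Lower in PebS were the thiosulphate-binding protein Synpcc7942_1681, at 50.4 ± 6.70 against 507 ± 249 TPM (-3.18 ± 0.31, adjusted p = 6.25e-05), and SigC (-2.53 ± 0.29, adjusted p = 0.000162). In total 671 genes differed, 562 higher in PebS and 109 lower, and 134 changed at least 2-fold, 102 higher and 32 lower. The median change was 0.27, and median-ratio scaling gave 377 genes, 162 higher and 215 lower (43.0% higher against 83.8%). At 2-fold the majority turned, with 34 higher and 88 lower under that scaling and 38 and 75 after quantile normalization. The count was 1330 with the block, 394 after quantile normalization, 647 within samples 2 and 3, and 447 without PebS 2.

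7 lists differed between PebS and PebAB, none of them with an estimated correlation. Nitrogen assimilation was higher in PebS, with 12 of 21 genes higher (14 adjusted over the list alone, 6 under median-ratio scaling; adjusted p = 0.00558 by camera, 0.220 with an estimated correlation). Lower relative to other genes was the ribosomal list (1 of 55 higher, the methyltransferase Synpcc7942_1500, 4 lower, 1 and 11 under median-ratio scaling; adjusted p = 0.000133 by camera, 0.104 with an estimated correlation). The same held for sigma factors (1 of 7 higher, 2 lower, 1 and 5 under median-ratio scaling; adjusted p = 0.00649 by camera, 0.282 with an estimated correlation). Oxidative stress genes were also lower (3 of 17 higher, 5 lower, 2 and 5 under median-ratio scaling; adjusted p = 0.0156 by camera, 0.220 with an estimated correlation). The plasmid-borne genes (1 of 40 higher, 1 lower, 0 and 5 under median-ratio scaling; adjusted p = 0.00624 by camera, 0.435 with an estimated correlation) and photosystem II (2 of 24 higher, 2 lower, 0 and 2 under median-ratio scaling; adjusted p = 0.0218 by camera, 0.220 with an estimated correlation) lost their calls under median-ratio scaling (adjusted p = 0.119 and 0.137). Chaperones (2 of 29 higher, 3 lower, 0 and 6 under median-ratio scaling; adjusted p = 0.0427 by camera, 0.220 with an estimated correlation) had a median of 0.07 and a mean of 0.01, opposite in sign to the test. That call was lost with the block (0.0599), within samples 2 and 3 (0.0987), without PebAB 1 (0.0577) and without PebS 1 (0.0599). With the block, phycocyanin rods (adjusted p = 0.00136 against 0.0524), allophycocyanin (0.0421 against 0.141), ATP synthase (0.00325 against 0.0726), the clock (0.0347 against 0.0524) and cytochrome b6f (0.0347 against 0.0551) also passed. With an estimated correlation added all 5 were lost (0.0551, 0.376, 0.139, 0.157 and 0.126). For the called lists, members higher and lower in PebS with the block numbered 6 and 5 in chaperones, 14 and 1 in nitrogen, 5 and 6 in oxidative stress, 2 and 5 in photosystem II, 4 and 8 in plasmid-borne genes, 8 and 19 in ribosomal proteins and 1 and 4 in sigma factors. The summed phycocyanin alpha had adjusted p = 0.123 (0.000488 with the block), and the summed psbA was lower in PebS (-0.95, adjusted p = 0.000145).

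In PcyX against PebAB, Synpcc7942_2026 was higher by 2.37 ± 0.15, adjusted p = 2.42e-06. The pilin-like gene Synpcc7942_2590 stood at 96.2 ± 20.5 against 21.2 ± 0.790 TPM (2.11 ± 0.22, adjusted p = 7.04e-05) and the acyltransferase Synpcc7942_1193 (chromosome 1221676 to 1222398) at 142 ± 13.9 against 33.4 ± 4.19 TPM (2.05 ± 0.15, adjusted p = 5.62e-06). SigC (-3.38 ± 0.29, adjusted p = 1.84e-05) and Synpcc7942_1681 (-3.21 ± 0.31, adjusted p = 4.02e-05) were lower in PcyX. In total 769 genes differed, 606 higher in PcyX and 163 lower, and 161 changed at least 2-fold, 71 higher and 90 lower. The median change was 0.28, and median-ratio scaling gave 421 genes, 159 higher and 262 lower (37.8% higher against 78.8%). At 2-fold that scaling gave 21 higher and 140 lower, and quantile normalization 30 and 121. The count was 1474 with the block, 468 after quantile normalization and 773 within samples 2 and 3. There were 5 lists called, none with an estimated correlation. ATP synthase was higher in PcyX (6 of 9 genes, 7 adjusted over the list alone, 2 under median-ratio scaling; adjusted p = 0.00900 by camera, 0.365 with an estimated correlation). Nitrogen assimilation was higher too (13 of 21 higher, 5 higher and 2 lower under median-ratio scaling; adjusted p = 0.0135 by camera, 0.357 with an estimated correlation; adjusted p = 0.0581 without PcyX 3). The clock was lower (3 of 4; adjusted p = 0.00223 by camera, 0.104 with an estimated correlation). Sigma factors were lower (2 of 7 lower, 1 higher, 4 and 0 under median-ratio scaling; adjusted p = 0.00900 by camera, 0.365 with an estimated correlation), and so were plasmid-borne genes (5 of 40 lower, 1 higher, 6 and 0 under median-ratio scaling; adjusted p = 0.00420 by camera, 0.492 with an estimated correlation). Called lists had members higher and lower in PcyX with the block as 14 and 2 in nitrogen, 4 and 10 in plasmid-borne genes and 1 and 4 in sigma factors. With the block, phycocyanin rods (0.00633 against 0.101), photosystem II (0.0332 against 0.0780) and oxidative stress (0.0399 against 0.0607) also passed. With an estimated correlation added they did not (0.105, 0.105 and 0.116). Within samples 2 and 3 they passed (0.0196, 0.0119 and 0.0253). Under median-ratio scaling the chaperones did (0.0125 against 0.0607).

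PcyX and PebS differed least. A gene listed as carbonate dehydratase (Synpcc7942_1423, chromosome 1476059 to 1477678) stood at 518 ± 26.3 against 289 ± 13.1 TPM in PcyX against PebS (0.84 ± 0.10, adjusted p = 0.00213). The large subunit of Rubisco (Synpcc7942_1426, chromosome 1479461 to 1480879), the CO2-fixing enzyme, stood at 4486 ± 373 against 2539 ± 254 TPM (0.82 ± 0.14, adjusted p = 0.0116). This call was lost without PcyX 1 (adjusted p = 0.0553), PebS 2 (0.0640) or PebS 3 (0.0626). Superoxide dismutase (Synpcc7942_0801) stood at 632 ± 139 against 349 ± 38.9 TPM (0.84 ± 0.14, adjusted p = 0.0130; 0.0626 without PebS 3 and 0.0780 within samples 2 and 3). IsiA (Synpcc7942_1542) was lower in PcyX, at 11344 ± 1159.6 against 24109.6 ± 3233 TPM (-1.08 ± 0.16, adjusted p = 0.00624). So were protoheme IX farnesyltransferase (Synpcc7942_2600, -1.05 ± 0.17, adjusted p = 0.00801) and cytochrome oxidase d subunit I (Synpcc7942_1767, -1.01 ± 0.15, adjusted p = 0.00624). With only these strains in the fit, adjusted p was 0.0825 for Synpcc7942_1426, 0.146 for Synpcc7942_0801, 0.0914 for Synpcc7942_1542, 0.134 for Synpcc7942_2600 and 0.0661 for Synpcc7942_1767.

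In total 53 genes differed between PcyX and PebS, 12 higher in PcyX and 41 lower, and 10 of them, introduced genes included, at least 2-fold. The count was 464 with the block, 103 with voom weights on recovered reads, 33 within samples 2 and 3 and 7 with only these strains in the fit. It was 25 without PebS 2 or PebS 3, 29 without PcyX 1, 33 without PebS 1 and 35 without PebAB 3 or PcyX 2. Ribosomal proteins were higher in PcyX, with 1 of 55 genes passing (6 adjusted over the list alone, 0 under median-ratio scaling) and a median 0.30 above that of all genes (adjusted p = 1.97e-12 by camera and 0.00455 with an estimated correlation). The clock was lower in PcyX, with 2 of 4 genes lower (3 adjusted over the list alone, 1 under median-ratio scaling; adjusted p = 0.000281 by camera and 0.0331 with an estimated correlation). ATP synthase (0 of 9 passing; adjusted p = 0.00193 by camera, 0.322 with an estimated correlation) and heme and bilin synthesis (0 of 12; adjusted p = 0.00650 by camera, 0.322 with an estimated correlation) were higher as lists. With the block and an estimated correlation the ribosomal list had adjusted p = 0.00862 and the clock lost its call (0.0757), while carbon fixation passed (0.0394). Also higher were carbon fixation (0 of 7 in the list without Rubisco and carbonate dehydratase; adjusted p = 0.0195 by camera, 0.101 with an estimated correlation; with them 3 of 10, 9 with the block, and adjusted p = 4.22e-06, 0.00895 with an estimated correlation) and cytochrome b6f (0 of 11; adjusted p = 0.0251 by camera, 0.101 with an estimated correlation). Without PcyX 3 these last had adjusted p = 0.0631 and 0.0631, and cytochrome b6f had 0.131 within samples 2 and 3 and 0.0559 without PebS 1. Glycogen and storage carbon (1 of 5 lower, 3 adjusted over the list alone; adjusted p = 0.00683 by camera, 0.0788 with an estimated correlation) and pili (3 of 12 lower, 1 under median-ratio scaling; adjusted p = 0.00193 by camera, 0.0613 with an estimated correlation) were lower in PcyX. In the called lists the block made members higher and lower in PcyX 7 and 0 in ATP synthase, 6 and 0 in carbon fixation, 3 and 0 in cytochrome b6f, 0 and 3 in glycogen, 5 and 0 in heme and bilins, 0 and 6 in pili and 34 and 1 in ribosomal proteins. The allophycocyanin list, at adjusted p = 0.262, passed with the block (0.0268, but 0.539 with an estimated correlation added), within samples 2 and 3 (0.0333) and without PebS 1 (0.0298). The phycocyanin rods had adjusted p = 0.877.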

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

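The search for genes that changed in opposite directions in 2 strains was restricted, after the comparisons had been seen, to genes named under the fixed rule whose difference between the strains passed the test. No explanation of these values was tested. Each strain has 3 samples, too few to test for a single sample far from the rest.

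A few reads of introduced genes stood in libraries of strains that do not carry them, where the WT libraries held none. PebB was at 1.20 TPM in PcyX 1 (1 read) and 0.311 TPM in PebS 2 (1 read). The pcyX_cme gene was at 1.45 TPM in PebS 2 (4 reads) and pebS_cme at 0.280 TPM in PcyX 2 (1 read).

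Several genes fell in PebAB and rose in another strain, each difference tested directly between the strains. The difference from PebAB was 2.37 in PcyX and 2.96 in PebS for the glycosyltransferase Synpcc7942_2026, 2.05 and 2.31 for the acyltransferase Synpcc7942_1193, and 2.57 in PebS for the fasciclin-domain gene Synpcc7942_1606. For nitrate transport subunits it was 1.17 and 1.26 (Synpcc7942_1236) and 1.35 and 1.37 (Synpcc7942_1237), and for the transport gene Synpcc7942_2107 0.87 and 0.66. Thioredoxin reductase Synpcc7942_0623 differed by 0.97 and 0.98, the ribosomal protein methyltransferase Synpcc7942_1500 by 0.97 and 0.95, glutamine synthetase Synpcc7942_0169 by 1.05 in PcyX and the ferredoxin-thioredoxin reductase chain Synpcc7942_1734 by 0.95 in PebS. The gene listed as carbonate dehydratase, Synpcc7942_1423, rose in PcyX and fell in both other strains. It was 0.98 higher in PcyX than in PebAB and 0.84 higher than in PebS.

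The signs were the same under median-ratio scaling, which removes the lower median of PebAB, but parts of the calls against WT were not. Adjusted p-values against WT under that scaling were 0.0947 (PebAB) and 0.298 (PcyX) for Synpcc7942_1423, 0.224 (PebAB) for Synpcc7942_1500, 0.300 (PebAB) and 0.205 (PebS) for Synpcc7942_1734, and 0.613 (PebAB) and 0.127 (PebS) for Synpcc7942_2107. They were 0.187 (PcyX) and 0.104 (PebS) for Synpcc7942_0623, 0.157 (PcyX) and 0.0781 (PebS) for Synpcc7942_1237 and 0.0878 (PcyX) for Synpcc7942_0169.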

How the results depend on the processing

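Some settings, named with the processing, were chosen after the data had been seen, and the others before. Of 515 alternative values of counts and correlations, 445 lay within 1.5 times or on the same side. Of 7445 alternative values for 267 results on named genes, 6955 kept their direction and side of the threshold, 401 no longer passed, 89 newly passed and 0 reversed. The replicate block let 21 named results newly pass and lost 0. It also changed calls of lists, given beside the results, and of further list members, given there as counts where these moved by over 1.5 times. Of summed copies, D2 newly passed with it in PebAB (adjusted p = 0.0165 against 0.432) and PebS (0.00898 against 0.444) over WT. So did psbA in PebS against WT (0.00191 against 0.158) and in PcyX against PebS (0.0168 against 0.488), phycocyanin alpha in PcyX against PebAB (0.000274 against 0.0886) and beta in PebS and PcyX against PebAB (0.000795 against 0.213 and 0.000597 against 0.186).

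Counts that moved are given for PebAB, PcyX and PebS against WT, then PebS against PebAB, PcyX against PebAB and PcyX against PebS. The replicate block gave 1325, 501, 892, 1330, 1474 and 464 changed genes, sample weights 1370, 317, 839, 1369, 1292 and 279, and voom with the block 1163, 406, 769, 1064, 1201 and 418. Median-ratio scaling gave 389 for PebAB against WT and 377 and 421 for PebS and PcyX against PebAB, where quantile normalization gave 394 and 468. For PcyX and PebS against WT and PcyX against PebS, the block with median-ratio scaling gave 474, 930 and 470, and only the strains compared 57, 221 and 7. For PcyX against PebS, samples 2 and 3 gave 33 and voom 103, and its 2-fold count of 10 became 22 with sample weights, 2 with only these strains, 19 with the block, 18 with voom and the block and 16 with the block and median-ratio scaling. The F-test gave 530 with median-ratio scaling, 1673 with sample weights, 1724 with the block, 1460 with voom and the block and 1381 with the block and median-ratio scaling. With an estimated correlation 0, 0, 2, 0, 0 and 2 lists were called, and with the block and an estimated correlation 0, 1, 1, 0, 0 and 2. Samples 2 and 3 gave 5 lists for PcyX against WT and 8 for PcyX against PebAB, and the block 11 and 8 for PebS and PcyX against PebAB. Calls changed by completing lists are given beside the results. Only the fatty acid, ribosomal and transposase lists were trimmed of other functions, and only the first lost a call, in PcyX against WT (0.0597). In all 3 strains 136 genes were higher and 73 lower with the block, 110 and 45 with sample weights, 109 and 78 with voom and the block, 138 and 60 with the block and median-ratio scaling and 34 and 5 with only the strains compared, and 26 were lower with voom. Fits of fewer samples have less information, but the cause was not tested.

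Leaving out each sample in turn gave 385 to 619, 99 to 151, 221 to 368, 447 to 674, 561 to 811 and 25 to 54 changed genes, 146 to 171, 50 to 62, 110 to 128, 124 to 148, 141 to 199 and 7 to 10 at 2-fold, and 615 to 814 by the F-test. Lists called ranged over 5 to 8, 6 to 8, 8 to 11, 7 to 9, 4 to 7 and 6 to 9. Genes higher in all 3 strains ranged from 51 to 57 and lower from 9 to 12 over the WT samples left out, and from 51 to 63 and 8 to 15 over all samples. Covariances, run for the WT samples alone, ranged from 0.165 to 0.184 (PebAB and PcyX), 0.256 to 0.280 (PebAB and PebS) and 0.199 to 0.222 (PcyX and PebS), where no change would reach at most 0.120, 0.141 and 0.122 by the highest simulated values scaled to 2 WT samples. Depth limits genes of few reads most in sample 1, where the median gene held 57 to 69 reads, and changes of 1.5-fold were recovered in 16.7% of simulated genes in PebAB against WT.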

Other observations

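The patterns weighed here had been seen before their tests were written, and the test on neighbouring genes, the counts within samples 2 and 3 and the genes singled out here were chosen only after the result or its values had been seen.

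Of the genes higher in all 3 strains, elongation factor EF-G Synpcc7942_2082 rose by 2.66 in PebAB, 1.76 in PcyX and 2.07 in PebS, and the RNA-binding protein Synpcc7942_1999 by 1.53, 1.23 and 1.39. The RNA polymerase genes Synpcc7942_1522 (0.95, 0.45 and 0.59) and Synpcc7942_1524 (1.08, 0.47 and 0.83) rose less. Among genes without a named function, Synpcc7942_0013 stood at 54.6 ± 10.4, 32.0 ± 6.59 and 32.7 ± 5.74 TPM in PebAB, PcyX and PebS against 291 ± 19.4 TPM in WT (SD, n = 3 each), a log2 change of -2.41, -3.16 and -3.13 with limma adjusted p = 6.69e-06, 2.57e-06 and 1.45e-06.

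Sample 1 of every strain stood apart from samples 2 and 3, and its differences from them correlated between strains at a mean r of 0.717 across genes. Thinning samples 2 and 3 to the depth of sample 1 made differences that correlated at 0.0890, which argues against depth. The near-identical phycocyanin copies Synpcc7942_1048 and Synpcc7942_1053 were split differently in sample 1 of every strain, at 56777 and 7848 TPM in WT 1 and at 30011 and 29758 TPM in WT 2, so sample 1 may have been counted differently. Without genes that share a product text the correlation was still 0.717, which argues against such copies as the whole, and coding length accounted for a share of 0.123 of the variance, which argues against a length bias as the whole. Different counting, handling or day of sample 1 stays open, and no biological explanation was tested because the design names none.

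More genes were lower than higher in PebAB, with a median change of -0.243. Leaving out 1 library moved that median no nearer 0 than -0.193, which argues against 1 odd library. The summed gain of the 10 genes with the largest gain came to 6.87% of all TPM, and without them the median was -0.126 with 212 genes higher and 232 lower. A few abundant transcripts taking a larger share could thus account for part of the shift, and this cannot be told apart from a true fall of many transcripts because TPM sums to a fixed total. A difference of the strain itself stays open and untested.

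The 64 genes higher in all 3 strains are unlikely to come from chance values shared through the WT libraries, since 100 simulated sets gave at most 0. They were still 51 in number without the WT sample that lowered the count most, and 58 within samples 2 and 3, which argues against 1 odd WT library and against the handling of sample 1. Of the 64, 33 had a neighbour on the same strand also among them, where 10000 random sets gave at most 14, so a candidate explanation for the size of the set is that co-transcribed genes were counted singly (44 separate stretches). An effect of the common vector or its insertion cannot be separated from an effect of the enzymes, since no strain with an empty vector is among the samples.

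For each comparison of 3 samples with 3 there are 10 splits, too few for a share under 0.05. With the other strains' samples kept in place, limma called 616 genes for PebAB, 151 for PcyX and 354 for PebS against WT, 671 for PebS and 769 for PcyX against PebAB and 53 for PcyX against PebS. The highest of the other splits was 0 in each (1 of 10 splits as large, the real one), both among those that part all same-numbered samples and among those that leave some together. For the F-test over 4 strains, the real grouping gave 817 genes and the highest other 184. Thus 1 of 100 groupings, the real one, reached that count. Those groupings ignored the sample numbers. Of 576 with a sample 1, 2 and 3 in each group, 100 were run. The highest other gave 555, and 1237 against a real 1724 with the block. In both fits only the real one was as large, so chance is unlikely.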
